A study of Rattus norvegicus with 20 samples.

How the data were processed

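RNA of neonatal rat heart cell cultures was measured on 20 single-colour Agilent arrays: 2 untreated and 3 of each of 6 celecoxib groups (reference concentrations of 1, 1/5 and 1/25 for 6 h or 24 h). The design text gives 3 replicates per group, while 2 untreated arrays were deposited. Each array had 43379 spots other than control spots, for 41012 probes. The deposited scanner files hold the fluorescence intensity of each spot in linear units, extracted with Agilent Feature Extraction 9.5.3.1 per the file headers. The deposited value table holds a linear ratio made by the authors. Checked against the scanner files, it is the processed signal, averaged over the spots of a probe, divided by the median of the array and by the mean of the 2 untreated arrays, with a floor that 15 of 820240 values reach. Its column medians ran from 0.826 to 1.27.

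The processed signal of the scanner files was taken to log2, and the log2 of the array's 75th percentile was subtracted. Spots that the scanner software marked as outliers were left out, and spots of the same probe were averaged. A probe was kept if it was well above background on every array of at least 1 group, which kept 31739 probes. Of the 41012 probes, 22560 were well above background on all 20 arrays and 3239 on none. Depth on arrays is the signal over background: 63.5% to 83.1% of probes per array were well above it. Changes of saturated probes are compressed, and a gene well above background on no array of a group is given as a bound against the lowest signal that was well above background.

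Probes were named from the RefSeq accession of the probe (10735 probes), from a current symbol or synonym (9224) or from another listed RefSeq accession (60), and 20993 kept the name in the file. Of all probes, 19979 had a gene symbol that did not start with LOC or RGD. The brightest kept probe stood for each gene, which left 27743 genes. Of these, 11824 had such a symbol and 3274 had more than 1 kept probe. In a comparison, genes without a value in a group were left out.

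All 20 arrays were fitted together with a mean for each of the 7 groups in limma 3.58.1 (R 4.3.3), with moderated, two-sided tests and 13 residual degrees of freedom (17.1 after moderation). The Benjamini-Hochberg adjustment ran over all genes of a comparison, and genes with an adjusted p below 0.05 were called. The 12 comparisons were each celecoxib group against untreated, concentration 1 against 1/25 at each time, 24 h against 6 h at each concentration, and the difference of the concentration effect between the times. The comparisons, tests, gene lists, naming rule and alternatives were chosen before the data were examined, except where stated. The tables were read with jsonlite 2.0.0 and the data.table package, version 1.17.8, and the correlation within slides (0.345) was computed with statmod 1.5.0.

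Gene lists written from general knowledge were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over 252 tests (28 lists in 9 comparisons: the 6 with untreated, both of concentration, and 24 h against 6 h at concentration 1). Camera with an estimated correlation and fry were run beside it. The lists were also tested in the other comparisons of 24 h with 6 h, adjusted over the 28 lists of each, which was chosen after seeing the data. Those that passed were tested again without each array and with slide as a random block. The lists covered prostanoid synthesis and receptors, sarcomere, calcium handling and ion channels, hypertrophy and natriuretic peptides, ATF4 and integrated stress response, endoplasmic reticulum chaperones, cytosolic heat shock, NRF2 oxidative stress, cholesterol synthesis, PPAR and fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, cell cycle, p53 targets, apoptosis regulators, inflammatory cytokines and NF-kappa-B, interferon response, immediate early genes, xenobiotic metabolism and transport, lysosome and autophagy, circadian clock, extracellular matrix and TGF-beta, and markers of fibroblasts, smooth muscle, endothelium, macrophages and leukocytes, erythroid cells, and epicardium and neural crest derived cells.

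Genes were named by rule. For concentration 1 against untreated, at each time, these were the 8 largest rises and 8 largest falls among called genes with a symbol that were well above background on every array of both groups and beyond both untreated arrays on all 3 treated arrays. For every other comparison the 3 largest rises and 3 largest falls were named by the same rule, and for each list that passed up to 4 members with the smallest adjusted p. Ptgs1, Ptgs2, Ptges, Ptgis and Ptger4 were named in any case.

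In simulated data with 200 of 27123 genes changed, the comparison of concentration 1 for 6 h with untreated recovered 0% of changes of 1 on the log2 scale, 56.5% of changes of 2 and 81% of changes of 3. Genes not changed were 2.59% and 4.14% of the calls at 2 and 3. For concentration 1 against 1/25 at 24 h the recoveries were 0%, 62.5% and 90%, with 6.02% and 7.69% of calls not changed. A simulated shift of 0.5 in the cell cycle list gave adjusted p = 7.2e-18 in camera, and 0 of the 27 other lists passed. The simulated genes varied independently, without correlation between genes and without shared effects of scan day or slide. These values therefore do not show how the list test behaves on the measured arrays, where genes are correlated.

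Set against these choices were normexp background correction (offset 50), quantile normalisation, no filter on dim probes, a filter that asks for all 20 arrays, the authors' table, the mean over the probes of a gene, slide as a random or a fixed block, only the arrays of a shared slide, replicate number as a block, only the groups compared, a trend over the 3 concentrations, an estimated correlation in camera, and leaving out each array in turn. Chosen after seeing the data were scan day as a block, with and without untreated replicate 1 and with quantile normalisation, and fits within each scan day. Control spots were left out, and no array was left out of the planned fits.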

Results

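RNA abundance was measured on single-colour microarrays in primary heart cell cultures of neonatal rats that had grown for 1 day. Celecoxib, an inhibitor of cyclo-oxygenase 2, was given for 6 h or 24 h at reference concentrations of 1, 1/5 and 1/25, whose absolute value the labels do not give. Of the 20 arrays, 2 were untreated and 3 came from each of the 6 celecoxib groups. Each array carried 41012 probes, of which 63.5% to 83.1% read well above background and 5.74% to 9.21% were saturated. The number of arrays limits the precision of every comparison. The untreated arrays carry no stated time or vehicle, so they are not matched in time to either celecoxib group. The labels do not say whether replicates were separate cultures, so each p-value measures only the spread between these samples, which may be technical.

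The arrays were scanned on 2 days, and the scan days parted them more strongly than the treatment did. The first principal component held 30.1% of the variance, and 97.9% of it lay between the scan days. Arrays of the same group had a mean correlation across genes of 0.961 within a scan day and 0.905 across the days, where genes are not independent replicates. Both untreated arrays and all 9 arrays of 24 h were scanned on day 1. All 3 arrays of celecoxib 1/5 for 6 h were scanned on day 2, with 1 array of celecoxib 1 for 6 h and 2 arrays of celecoxib 1/25 for 6 h. The untreated arrays lay on slide 1 with 2 arrays of celecoxib 1 for 6 h, and the arrays of 24 h lay on slides 2, 3 and 4. Apart from celecoxib 1 for 6 h and untreated, no slide held both groups of a comparison, so slide and treatment, time or concentration coincide there. The correlation within slides was 0.345. No slide was scanned on both days and that fit had no term for scan day, so this value can include the difference between days. Untreated replicate 1 and celecoxib 1/25 for 6 h replicate 3 also stood apart. For the untreated array, the 75th percentile was 4.07 times the median signal against at least 4.96 on the other 19 arrays, and the mean correlation with the others was 0.887. For the celecoxib array the ratio was the highest of the 20 at 7.0, the mean correlation was 0.888, and the array lay at the end of components 1, 3 and 4 (113, 67.7 and 70.3).

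**Figure D1:**
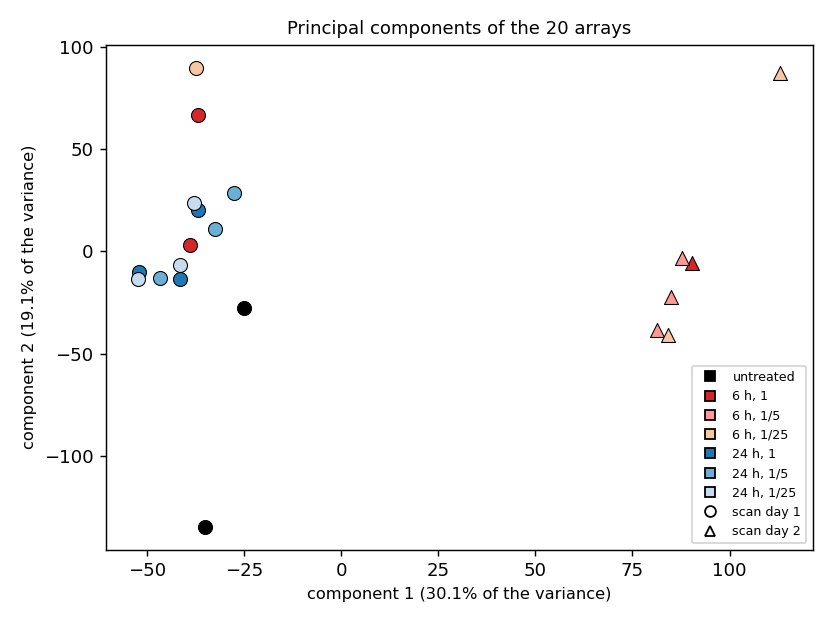
Principal components 1 and 2 of log2 signal over 27123 genes, 1 point per array, with the group shown by colour and the scan day by marker. Component 1 (30.1% of the variance) parts the scan days and component 2 (19.1%) has untreated replicate 1 at its end.

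Celecoxib at concentration 1 for 6 h was compared with untreated cultures to see which genes respond early to the drug. Gldn, which encodes the cell adhesion protein gliomedin, rose by 4.24 ± 0.30 on the log2 scale (SE, 3 arrays against 2), which is 18.9-fold. Among the other 7 rises named were Tfpi2, a serine protease inhibitor (3.06 ± 0.44), Ctss, the lysosomal protease cathepsin S (2.46 ± 0.40), and Nes, the intermediate filament protein nestin (2.19 ± 0.35). Olr1, a receptor for oxidised low-density lipoprotein, rose by 2.53 ± 0.38 with 2 of 3 treated arrays saturated, and Tnfrsf11b, a decoy receptor of the tumour necrosis factor receptor family, by 2.49 ± 0.39 with 1 of 3 saturated. Akap12, a kinase scaffold protein, rose by 2.00 ± 0.39 and Mmp12, a matrix metalloprotease, by 1.88 ± 0.36. Hs3st1, a heparan sulfate sulfotransferase, fell (log2 change -3.02 ± 0.49), as did Pkp1, a desmosome protein (-2.27 ± 0.48), Slit1, a guidance ligand (-2.24 ± 0.45), and Agxt, a peroxisomal aminotransferase (-2.13 ± 0.41). Sfta2 (-2.01 ± 0.42), Rnase4 (-1.90 ± 0.38), Masp2 (-1.81 ± 0.38) and Hmx2 (-1.74 ± 0.36) completed the named falls.

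In limma, 119 of 27734 genes passed an adjusted p of 0.05 in this comparison, 35 higher and 84 lower than untreated. The adjusted p of the 16 named genes ran from 2.4e-06 for Gldn to 0.0493 for Pkp1, and on all 3 treated arrays each of them lay beyond both untreated arrays. Blocking by scan day gave 2276 genes, with all 16 named genes past, and within scan day 1 the count was 1582. Without untreated replicate 1 it was 5, and of the 16 genes Gldn alone passed, at 4.11. With 1 untreated array left the other 15 kept their direction, with Tfpi2 at 2.70, Tnfrsf11b at 2.31, Olr1 at 2.25, Nes at 2.01 and Pkp1 at -1.44, and adjusted p of 0.138, 0.171, 0.146, 0.195 and 0.669. Slide as a random block gave 431, with all 16 genes past. With slide as a fixed block Pkp1 (-2.14, adjusted p = 0.0594) and Rnase4 (-1.78, 0.0508) did not pass in limma, and the other named genes did. The count was 865 without untreated replicate 2, and 20, 72 and 381 without treated replicates 1, 2 and 3, where 14, 4, 7 and 14 of the 16 genes passed. Quantile normalisation moved the share of called genes that were lower from 70.6% to 48.5%, so the balance of higher and lower genes depends on the scaling.

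**Figure D2:**
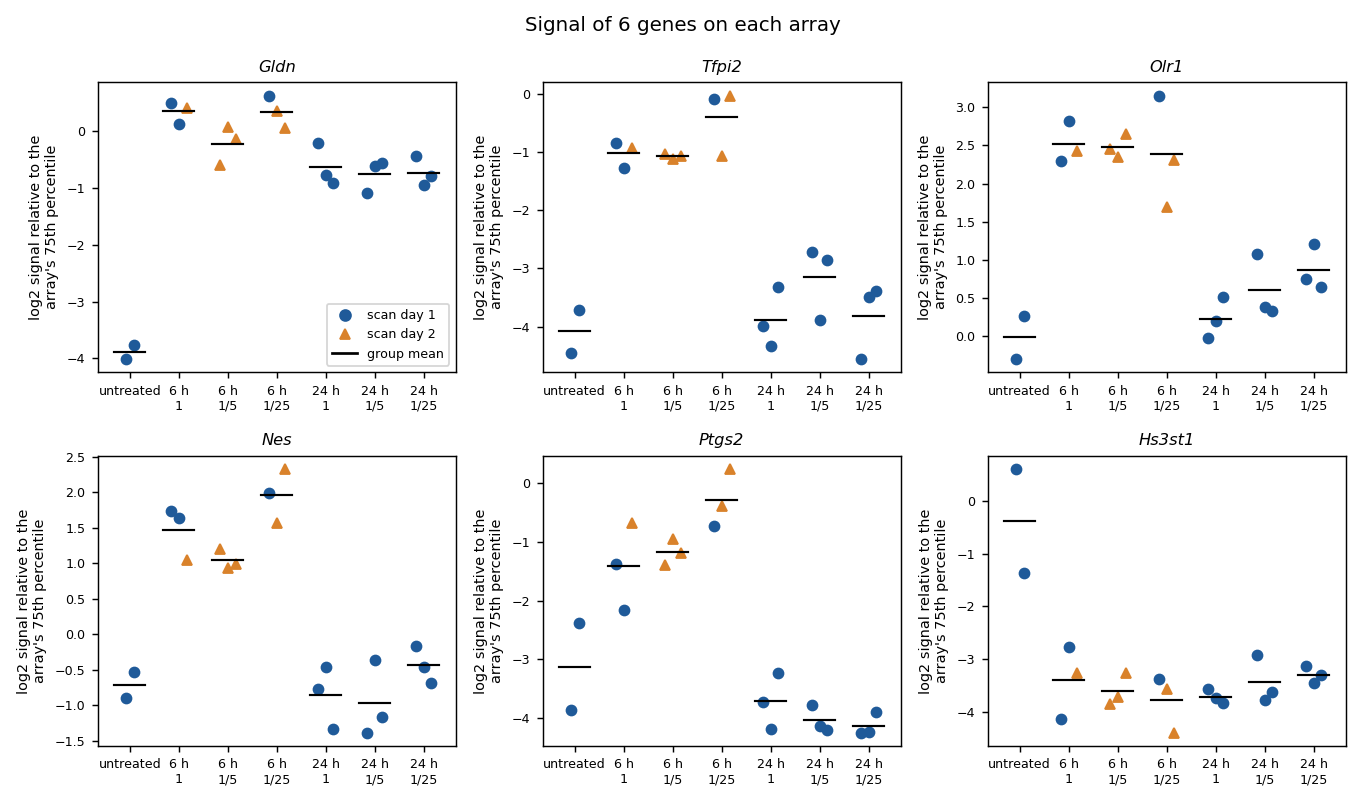
Log2 signal relative to the array's 75th percentile for named genes on each of the 20 arrays, by group, with group means as bars and scan days as markers. Gldn lies higher on all celecoxib arrays than on both untreated arrays, by 3.14 to 4.24 on the log2 scale per group.

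Celecoxib at concentration 1/5 for 6 h gave the largest count of the planned fits, on arrays that were all scanned on day 2. With scan day as a block its count was the smallest of the 3 concentrations at 6 h. Gldn rose by 3.67 ± 0.30 on the log2 scale (SE, 3 arrays against 2) and Hs3st1 fell by 3.23 ± 0.49, as they did at concentration 1. Kiaa0408L fell by 3.06 ± 0.79, and these 3 genes also passed with scan day as a block, Kiaa0408L at -4.77. Svs6, a seminal vesicle secretory protein gene, read 4.16 ± 1.16 higher, Slc7a8, an amino acid transporter gene, 3.70 ± 0.78 higher, and Slc18b1 had a log2 change of -2.77 ± 0.68. With scan day as a block these changes were 0.00 for Svs6, 0.94 for Slc7a8 and -2.61 for Slc18b1, with adjusted p of 0.997, 0.237 and 0.154.

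In limma, 1817 of 27735 genes passed at 1/5 for 6 h, 1227 higher and 590 lower, with adjusted p of 2.2e-05 for Gldn and 0.0422 for Svs6. Blocking by scan day gave 317, of which 60 were called in the same direction without the block. No array of this group was scanned on day 1, so there is no value within a scan day. The count was 7 without untreated replicate 1, and 196, 61 and 38 without treated replicates 1, 2 and 3. Gldn passed whichever of the 5 arrays was left out. Without untreated replicate 1 it was the only one of the 6 named genes to pass, with Hs3st1 at -2.25 (adjusted p = 0.115), Kiaa0408L at -2.21 (0.327) and Slc18b1 at -1.68 (0.346), and this was also so with scan day as a block. Hs3st1 read 0.61 on untreated replicate 1 and -1.37 on replicate 2, in log2 relative to the 75th percentile. Of the 6 genes 5 passed without untreated replicate 2, and Gldn and Hs3st1 passed without each treated replicate. Slide as a random block gave 3 and as a fixed block 2, and in both Gldn alone of the 6 passed.

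With celecoxib 1/25 for 6 h, Gldn read 4.24 ± 0.30 and Tfpi2 3.68 ± 0.44 higher than untreated on the log2 scale (SE, 3 arrays against 2). Slc7a8 rose by 3.21 ± 0.78, or by 1.37 with scan day as a block. Hs3st1 fell by 3.40 ± 0.49 and Sctr, the secretin receptor gene, by 3.11 ± 0.67. Dnajc6, a clathrin uncoating factor gene, fell by 3.70 ± 0.95, although 1 of its 3 probes had the other sign. Its adjusted p was 0.0518 with scan day as a block.

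In limma, 1662 of 27736 genes passed at 1/25 for 6 h, 623 higher and 1039 lower, with adjusted p of 2.4e-06 for Gldn and 0.00116 for Tfpi2. The count was 3211 with scan day as a block, and within scan day 1, with 1 treated array, it was 2545. Without untreated replicate 1 it was 15, Gldn and Tfpi2 being the named genes that passed, and Sctr was at -1.81 (adjusted p = 0.347). With slide as a random block it was also 15, and of the named genes Gldn and Tfpi2 passed. The count was 3027 without untreated replicate 2, and 3704, 4621 and 117 without treated replicates 1, 2 and 3. Without treated replicate 3, Gldn, Tfpi2 and Hs3st1 were the named genes that passed. Quantile normalisation moved the share of lower genes from 62.5% to 36.0%.

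The gene of the drug's target, Ptgs2 (cyclo-oxygenase 2), read higher than untreated at 6 h on all 3 arrays of each concentration. The log2 change was 1.72 ± 0.45 at concentration 1 (adjusted p = 0.0903 in limma), 1.94 ± 0.45 at 1/5 (0.0267) and 2.83 ± 0.45 at 1/25 (0.00708). With scan day as a block it was 1.43, 1.07 and 2.24 (adjusted p of 0.0447, 0.270 and 0.0110), and without untreated replicate 1 it was 0.98, 1.2 and 2.09 (0.896, 0.314 and 0.135). At 24 h Ptgs2 did not pass at any concentration, with log2 changes of -0.58 at concentration 1, -0.91 at 1/5 and -1.0 at 1/25. Ptgs1, Ptges and Ptgis, which encode other enzymes of prostanoid synthesis, did not pass in any of the 12 comparisons. At concentration 1 the log2 change at 6 h and 24 h was 0.33 ± 0.25 and 0.25 ± 0.25 for Ptgs1, -0.69 ± 0.34 and -0.31 ± 0.34 for Ptges, and -0.10 ± 0.36 and -0.18 ± 0.36 for Ptgis. Single arrays moved some of these: Ptges at 6 h was at -0.34 and -1.04 without untreated replicates 1 and 2. Ptgis at 24 h was at -0.41 and -0.0022 without treated replicates 2 and 3. Ptger4, a prostaglandin E2 receptor gene, was well above background on 0 arrays and was not tested.

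Celecoxib at concentration 1 for 24 h was compared with untreated cultures to see which changes are present after a day. Gldn rose by 3.26 ± 0.30 on the log2 scale (SE, 3 arrays against 2) and Cd83, an immunoglobulin family protein of activated immune cells, by 2.20 ± 0.32. Hs3st1 fell by 3.33 ± 0.49, Slit1 by 2.88 ± 0.45 and Neurog2, a neural transcription factor gene, by 2.78 ± 0.47. These 5 were all the genes that met the naming rule. Of the 42 cell cycle genes tested, 33 read above untreated, with a median log2 change of 0.51 and the list's mean higher on 3 of 3 arrays. Camera in limma gave adjusted p = 0.000602 for this list, and adjusted p = 0.191 with an estimated correlation. No member passed over all genes tested, and 2 passed, both higher, when adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, had a log2 change of 1.46 ± 0.31 (adjusted p = 0.0846), Nusap1 1.34 ± 0.36, Kif11 1.55 ± 0.49 and Aurkb -1.75 ± 0.56, with 1 of 2 Aurkb probes of the other sign. Kif11 was at 0.70 without untreated replicate 2 and at 2.40 without untreated replicate 1, where Aurkb was at -1.11.

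In limma, 18 of 27735 genes passed at concentration 1 for 24 h, 2 higher and 16 lower, with adjusted p of 0.000137 for Gldn and 0.0122 for Cd83. No 24 h array shares a slide with the untreated arrays, and slide as a random block gave 3 genes, with Gldn the only named gene past. There were 125 with scan day as a block, and within scan day 1 it was 38. It was 4 without untreated replicate 1, 244 without untreated replicate 2, and 9, 7 and 6 without treated replicates 1, 2 and 3. Of the 5 named genes, Gldn alone passed without untreated replicate 1, where Cd83 was at 2.48 (adjusted p = 0.0633), Hs3st1 at -2.35 (0.186), Slit1 at -2.41 (0.233) and Neurog2 at -2.95 (0.186). Without untreated replicate 2 all but Neurog2 passed, and without treated replicates 1, 2 and 3 there were 3, 1 and 2. The cell cycle list lost its call without untreated replicate 2 (median 0.48, adjusted p = 0.0719). Quantile normalisation moved the share of lower genes from 88.9% to 57.1%.

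With celecoxib 1/5 for 24 h, Gldn read 3.14 ± 0.30 higher than untreated on the log2 scale (SE, 3 arrays against 2). Ctss read 2.30 ± 0.40 higher and Ppp4r3a, a phosphatase subunit gene, 2.02 ± 0.36 higher. Sctr fell by 3.34 ± 0.67, Dhx9, an RNA helicase gene, by 3.22 ± 0.58, and Hs3st1 by 3.06 ± 0.49. Of the 42 cell cycle genes, 30 read above untreated, with a median of 0.44, adjusted p = 0.00342 in camera and adjusted p = 0.324 with an estimated correlation. No member passed over all genes tested, and adjusted over the list alone 4 were higher and 1 lower. Kif11 had a log2 change of 2.03 ± 0.49, Ttk of 1.38 ± 0.36 and Bub1 of 1.35 ± 0.35. Rrm1 had one of -1.26 ± 0.35, with 2 of its 3 probes of the other sign. Without untreated replicate 2 Kif11 was at 1.18.

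In limma, 79 of 27734 genes passed at 1/5 for 24 h, 16 higher and 63 lower, with adjusted p of 0.000235 for Gldn and 0.0445 for Sctr. Slide and treatment coincide, and slide as a random block gave 4 genes, with Gldn the only named gene past. There were 388 with scan day as a block, and within scan day 1 it was 226. It was 11 without untreated replicate 1, 247 without untreated replicate 2, and 11, 52 and 27 without treated replicates 1, 2 and 3. Of the 6 named genes, Gldn and Dhx9 passed without untreated replicate 1, where Ctss was at 2.01, Ppp4r3a at 1.85, Sctr at -2.03 and Hs3st1 at -2.07 (adjusted p of 0.233, 0.233, 0.492 and 0.219). Without untreated replicate 2 all but Dhx9 passed, and without treated replicates 1, 2 and 3 there were 2, 5 and 1. The cell cycle list lost its call without untreated replicate 2 (adjusted p = 0.0899) and without treated replicate 2 (0.0512). Quantile normalisation moved the share of lower genes from 79.7% to 53.4%.

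With celecoxib 1/25 for 24 h, Gldn read 3.16 ± 0.30 higher than untreated on the log2 scale (SE, 3 arrays against 2). Cd83 read 2.40 ± 0.32 higher and Ctss 2.10 ± 0.40 higher. Hs3st1 fell (log2 change -2.92 ± 0.49), as did Pkp1 (-2.80 ± 0.48) and Or4c15, an olfactory receptor gene (-2.78 ± 0.47). Of the 42 cell cycle genes, 34 read above untreated, with a median of 0.35, adjusted p = 7.5e-05 in camera and adjusted p = 0.129 with an estimated correlation. No member passed over all genes tested or adjusted over the list alone. Kif11 had a log2 change of 1.63 ± 0.49, Top2a of 1.06 ± 0.33, Plk1 of 0.92 ± 0.29 and Rrm1 of -1.11 ± 0.35. Kif11 was at 2.48 and 0.78 without untreated replicates 1 and 2. Over the alternatives Plk1 ran from 0.37 to 1.22, Top2a from 0.90 to 1.36 and Rrm1 from -1.35 to -0.09.

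In limma, 80 of 27735 genes passed at 1/25 for 24 h, 13 higher and 67 lower, with adjusted p of 0.000218 for Gldn and 0.00563 for Cd83. Slide and treatment coincide, and slide as a random block gave 3 genes, with Gldn the only named gene past. There were 237 with scan day as a block, and within scan day 1 it was 203. It was 18 without untreated replicate 1, 231 without untreated replicate 2, and 38, 19 and 8 without treated replicates 1, 2 and 3. Of the 6 named genes, Gldn and Cd83 passed without untreated replicate 1, where Ctss was at 1.80, Hs3st1 at -1.93, Pkp1 at -1.96 and Or4c15 at -2.14 (adjusted p of 0.335, 0.269, 0.328 and 0.264). Without treated replicates 1, 2 and 3 there were 5, 2 and 2. Quantile normalisation moved the share of lower genes from 83.8% to 59.8%. The 6 comparisons with untreated share the same 2 untreated arrays, so they are not independent of each other. These arrays have no stated time or vehicle. Vehicle and time in culture are therefore not separated from the drug for Gldn or any other gene compared with untreated.

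**Figure D3:**
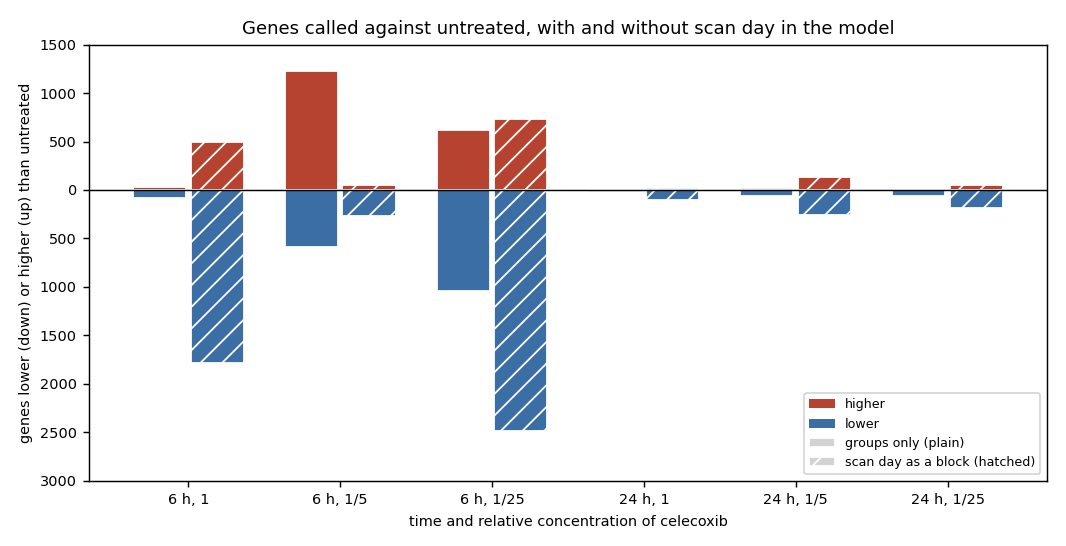
Number of genes with an adjusted p below 0.05 in limma for each of the 6 celecoxib groups against untreated, higher upwards and lower downwards, as planned (plain bars) and with scan day as a block (hatched bars). For celecoxib 1/5 for 6 h the count is 1817 as planned, 1227 higher and 590 lower, and 317 with the block.

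Concentration 1 was compared with 1/25 at each time to see which genes depend on the concentration over a 25-fold range. At 24 h, 26 of the 29 genes tested of the ATF4 and integrated stress response list read higher at concentration 1, with a median log2 difference of 0.32. Camera gave adjusted p = 0.00191 for this list, and adjusted p = 0.512 with an estimated correlation. No member passed over all genes tested, and 1 passed, higher, when adjusted over the list alone. Slc7a5, an amino acid transporter, read 1.37 ± 0.28 higher (SE, 3 arrays against 3, adjusted p = 0.801), Atf3, a stress-induced transcription factor, 1.04 ± 0.36 higher, Slc3a2, the partner of Slc7a5, 0.59 ± 0.35 higher, and Ppp1r15a, a phosphatase regulator, 0.50 ± 0.33 higher. The mean of the list lay above all arrays of 1/25 on 2 of 3 arrays of concentration 1, and the call was lost without replicate 3 of 1/25 (median 0.26, adjusted p = 0.0511). Without replicate 1 of concentration 1 the median was 0.18 (adjusted p = 0.0389). Concentration and slide coincide here, since the arrays of concentration 1 lay on slides 2 and 3 and those of 1/25 on slide 4. With slide as a fixed block, which rests on the arrays of 1/5 on slides 3 and 4, the list had a median of 0.33 and did not pass (adjusted p = 0.148). In the fit with the fixed block Slc7a5 was at 1.24, Atf3 at 0.67, Slc3a2 at 1.70 and Ppp1r15a at -0.16. The adjusted p of the list ran from 0.000391 to 0.512 over the alternatives.

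In limma, 0 genes passed between concentrations 1 and 1/25 at 6 h and 0 at 24 h, while 1749 and 816 had an unadjusted p below 0.05. Blocking by scan day gave 0 and 2, and within scan day 1 both were 0. Within scan day 2 the count at 6 h was 0. At 6 h, 24 genes passed without replicate 3 of concentration 1 and 1 without replicate 2 of 1/25. In simulated data of the 24 h comparison, genes varied independently and without shared effects of scan day or slide. The test recovered 0%, 62.5% and 90% of genes changed by 1, 2 and 3 on the log2 scale. The difference between the concentration effects at 24 h and 6 h gave 0 genes in limma, with 983 at an unadjusted p below 0.05, 0 with scan day as a block and 0 within scan day 1. Without replicate 3 of concentration 1 at 6 h it gave 2.

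At concentration 1, cultures of 24 h were compared with those of 6 h, which sets 3 arrays against 3 and uses no untreated array. Gjb2, a gap junction protein, rose by 1.80 ± 0.33 on the log2 scale, Rerg, a Ras-like protein, by 1.67 ± 0.32, and Chchd6, a mitochondrial inner membrane protein, by 1.65 ± 0.28. Tfpi2 fell by 2.86 ± 0.40, Dlx5, a homeobox gene, by 2.67 ± 0.47, and Itga2, a collagen receptor subunit, by 2.36 ± 0.41. Ptgs2 fell by 2.30 ± 0.40 (adjusted p = 0.0222). Of the 42 cell cycle genes, 36 read higher at 24 h, with a median of 0.47, adjusted p = 7.5e-05 in camera and adjusted p = 0.129 with an estimated correlation. Mcm6, a helicase subunit of DNA replication, rose at least 3.14-fold (adjusted p = 0.0156), since it was well above background on no array of 6 h, and it was the only member past the threshold over all genes tested or adjusted over the list alone. Rrm2 had a log2 change of 0.85 ± 0.27, Plk1 of 0.75 ± 0.26 and Tpx2 of 1.21 ± 0.47, or 0.71 with scan day as a block. The list had a median of 0.43 with scan day as a block (adjusted p = 0.000621) and of 0.49 within scan day 1 (0.000414). Over the same arrays the mean of 20 fibroblast markers was 0.31 ± 0.12 higher at 24 h, with a median of 0.02. The means of the markers of fibroblasts, of macrophages and leukocytes (median 0.33) and of epicardium and neural crest derived cells (0.23) lay higher on all 3 arrays of 24 h than on all 3 of 6 h, and those of smooth muscle (0.10), endothelium (-0.24) and erythroid cells (0.02) did not. None of these 6 marker lists passed. Chosen after seeing the data, the cell cycle list was also tested between the times at the other concentrations. At 1/25 it passed, with a median of 0.54 (adjusted p = 9.2e-05 over 28 lists, 0.0492 with an estimated correlation), and with scan day as a block the median was 0.63 (0.000206). The list's mean was -0.65 on replicate 3 of 1/25 for 6 h, which stood apart, against -0.26 and -0.23 on replicates 1 and 2. Without that array the median was 0.47 (1.5e-05). In the same comparison the means of the marker lists of macrophages and leukocytes, smooth muscle, fibroblasts, and epicardium and neural crest derived cells also lay higher on all 3 arrays of 24 h than on all 3 of 6 h, with medians of 0.55, 0.22, 0.10 and 0.08 (adjusted p of 0.405, 0.260, 0.543 and 0.839). At 1/5 it did not pass, with a median of 0.28 (0.181), or 0.26 with the block (0.387).

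Of 28 lysosome and autophagy genes, 23 read higher at 24 h of concentration 1, with a median of 0.30, adjusted p = 0.0216 in camera and adjusted p = 0.946 with an estimated correlation. No member passed over all genes tested or adjusted over the list alone. Hexa, a lysosomal hexosaminidase subunit, had a log2 change of 0.90 ± 0.30, Atp6v0d1, a proton pump subunit, of 0.94 ± 0.33, Mcoln1, a lysosomal channel, of 0.94 ± 0.34, and Tfeb, a transcription factor of lysosomal genes, of 0.61 ± 0.22. Without replicate 1 of 24 h Atp6v0d1 was at 0.56. The call was lost with scan day as a block (median 0.15, adjusted p = 0.366), within scan day 1 (0.10, 0.490), without replicate 3 of 6 h (0.10, 0.477) and without replicate 2 of 24 h (0.17, 0.123). In the same comparison, 10 of 15 macrophage and leukocyte markers read higher, with a median of 0.33 (adjusted p = 0.540) and the list's mean higher on all 3 arrays of 24 h than on all 3 of 6 h. Their median was 0.38 with scan day as a block and 0.26 within scan day 1. Between the times at the other concentrations, chosen after seeing the data, the lysosome list passed at 1/5 (0.56, adjusted p = 0.0244). It did not pass there with an estimated correlation (0.659), with scan day as a block (0.17, 0.637) or without replicate 2 of 24 h (0.56, 0.0679), nor at 1/25 (0.30, 0.260). At 1/5 the means of the markers of fibroblasts, smooth muscle, macrophages and leukocytes, and epicardium and neural crest derived cells also lay higher on all 3 arrays of 24 h than on all 3 of 6 h, with medians of 0.39, 0.35, 0.25 and 0.52 (adjusted p of 0.144, 0.335, 0.623 and 0.623), and there the times follow the scan days exactly.

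In limma, 49 of 27740 genes passed between 24 h and 6 h at concentration 1, 16 higher and 33 lower at 24 h, with adjusted p of 0.00486 for Tfpi2 and 0.0381 for Rerg. At this concentration no slide holds arrays of both times, and slide as a random block gave 3 genes, none of them a named gene, with Tfpi2 at -2.85 (adjusted p = 0.0863). With only the groups compared it was 1. The count was 389 with scan day as a block, which included all 49, and within scan day 1 it was 182. It was 20 without replicate 1 of 6 h, and 15 and 6 without replicates 1 and 2 of 24 h. Of the 7 named genes with Mcm6, 1, 4 and 5 passed without replicates 1, 2 and 3 of 6 h, and 2, 0 and 3 without those of 24 h. Quantile normalisation moved the share of lower genes from 67.3% to 52.2%, and under it Gjb2 and Dlx5 had adjusted p of 0.0596 and 0.0709.

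**Figure D4:**
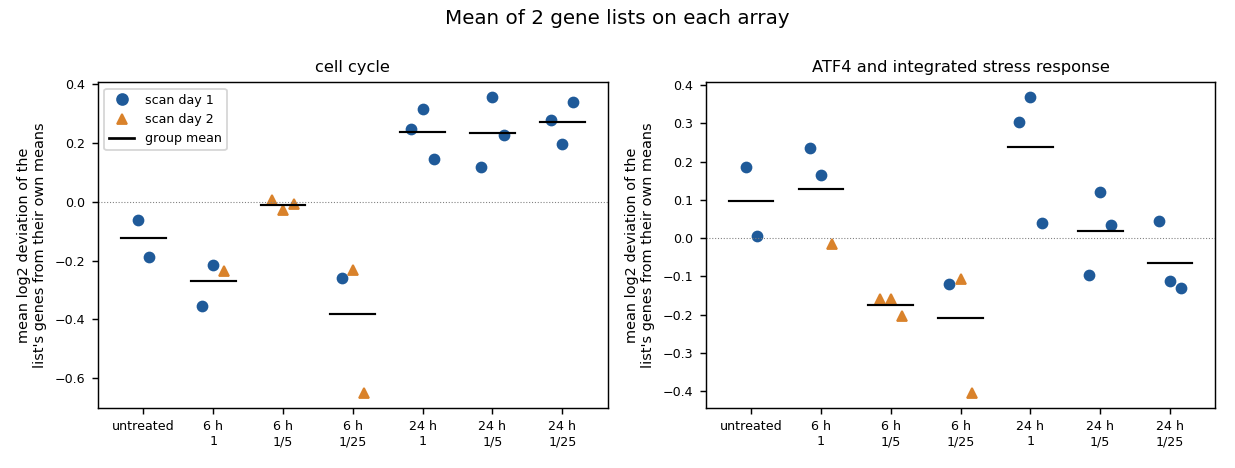
Mean log2 deviation of gene lists on each of the 20 arrays, by group, with group means as bars and scan days as markers. The mean of the cell cycle list is -0.27 in celecoxib 1 for 6 h and 0.24 in celecoxib 1 for 24 h.

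At concentration 1/5 the comparison of 24 h with 6 h follows the scan days exactly, since the 6 h arrays were scanned on day 2 and the 24 h arrays on day 1. Here too the block takes the difference between days from the other 6 h groups, so its estimates are less precise. Read without the block, Akr1c1, an aldo-keto reductase gene, was 3.22 ± 0.43 higher on the log2 scale (SE, 3 arrays against 3), Myh6, the alpha myosin heavy chain gene, 2.81 ± 0.73 higher with 1 of 3 arrays of 24 h saturated, and Klf15, a transcription factor gene, 2.54 ± 0.38 higher. Svs6 had a log2 change of -4.44 ± 1.03, Slc7a8 of -4.03 ± 0.70 and Clba1 of -3.48 ± 0.90. None of these 6 passed with scan day as a block, where Akr1c1 was at 2.12 (adjusted p = 0.155), Klf15 at 1.52, Myh6 at 0.86, Slc7a8 at -1.27, Svs6 at -0.29 and Clba1 at 0.18. In limma, 1356 of 27740 genes passed, 488 higher and 868 lower, with adjusted p of 0.00219 for Akr1c1. Blocking by scan day gave 10, of which 6 were also called without the block, slide as a random block gave 8 with none of the 6 past, and no value within a scan day can be had. The count was 57, 34 and 37 without replicates 1, 2 and 3 of 6 h, and 72, 63 and 148 without those of 24 h. Akr1c1 and Klf15 passed whichever of the 6 arrays was left out.

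At concentration 1/25, H1f1, a linker histone gene, was 2.73 ± 0.69 higher at 24 h than at 6 h on the log2 scale (SE, 3 arrays against 3). Dhrs3, a retinal reductase, rose by 2.71 ± 0.38 and Vldlr, a lipoprotein receptor, by 2.44 ± 0.43. Slc7a8 fell by 3.44 ± 0.70, or by 1.60 with scan day as a block, Tfpi2 by 3.41 ± 0.40, and Gfra2, a neurotrophic factor receptor, by 2.92 ± 0.39. With scan day as a block H1f1 had adjusted p = 0.192 and the other 5 passed. In limma, 681 of 27742 genes passed, 299 higher and 382 lower, with adjusted p of 0.000588 for Tfpi2. Time and slide coincide here too. Slide as a random block gave 13 genes, with Tfpi2, Gfra2 and Dhrs3 past, and as a fixed block 0. The count was 637 with scan day as a block, with 171 genes called in both, and 334 within scan day 1. It was 4265, 1051 and 94 without replicates 1, 2 and 3 of 6 h, and 55, 225 and 100 without those of 24 h. Dhrs3, Tfpi2 and Gfra2 passed whichever of the 6 arrays was left out.

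The other 25 of the 28 gene lists did not pass in any of the 9 comparisons planned for lists, among 252 tests. The smallest adjusted p was 0.117 for endoplasmic reticulum chaperones (median 0.21, 1/25 for 6 h) and for the interferon response (0.23, 24 h against 6 h of concentration 1). It was 0.214 for inflammatory cytokines and NF-kappa-B (-0.19), 0.409 for extracellular matrix and TGF-beta (0.28), and 0.433 for immediate early genes (0.18), oxidative phosphorylation (0.08), prostanoid synthesis and receptors (-0.11), fibroblast markers (0.13) and erythroid markers (-0.89). It was 0.459 for PPAR and fatty acid oxidation (0.17). It was 0.540 for markers of endothelium (-0.33), of macrophages and leukocytes (0.33) and of smooth muscle (-0.13), and for xenobiotic metabolism and transport (-0.64). It was 0.588 for the circadian clock (0.29), cytosolic heat shock (0.15) and hypertrophy and natriuretic peptides (0.28), and 0.592 for p53 targets (0.16). It was 0.641 for calcium handling and ion channels (-0.51), 0.715 for NRF2 oxidative stress (-0.28) and 0.826 for glycolysis and hypoxia (-0.28). It was 0.717 for apoptosis regulators (0.08), cholesterol synthesis (-0.09), sarcomere (0.09) and markers of epicardium and neural crest derived cells (-0.25). None of the 28 lists passed with an estimated correlation in these comparisons. In fry, the cell cycle list had adjusted p = 0.0797 at each concentration for 24 h against untreated and 0.0233 for 24 h against 6 h, and the ATF4 and lysosome lists had 0.133.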

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

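The tests of untreated replicate 1 on dim genes, and of scan day and concentration on the cell cycle list, were chosen only after the result was seen, as were all fits with scan day as a block.

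Among the genes named and called against untreated, with Ptgs2 added, the log2 effect against untreated differed between 24 h and 6 h for 9. This was tested in limma by 24 h against 6 h at the same concentration (3 arrays against 3), where the untreated arrays drop out. Over all genes tested, the same comparisons called 49 genes at concentration 1, 1356 at 1/5 and 681 at 1/25. At concentration 1 the effect at 24 h minus that at 6 h was -2.33 ± 0.32 for Nes (adjusted p = 0.00478), -2.29 ± 0.34 for Olr1 (0.00743), -2.30 ± 0.40 for Ptgs2 (0.0222) and -2.86 ± 0.40 for Tfpi2 (0.00486), and all 4 passed with scan day as a block. At 1/25 it was 1.54 ± 0.29 for Cd83 (0.0145), -1.08 ± 0.27 for Gldn (0.0457), -3.83 ± 0.40 for Ptgs2 (0.000312), -3.44 ± 0.70 for Slc7a8 (0.0221) and -3.41 ± 0.40 for Tfpi2 (0.000588). With the block these 5 also passed, except Gldn (-1.19, adjusted p = 0.0585). At 1/5, where time and scan day coincide, it was 1.36 ± 0.32 for Ppp4r3a (0.0345), -2.85 ± 0.40 for Ptgs2 (0.00347), -4.03 ± 0.70 for Slc7a8 (0.0119) and -4.44 ± 1.03 for Svs6 (0.0333). None of these 4 passed with the block, at 1.43, -1.98, -1.27 and -0.29. Time and slide coincide at each concentration. With slide as a random block, chosen here after seeing the data, Ptgs2 (-3.71, adjusted p = 0.0117) and Tfpi2 (-3.58, 0.0205) at 1/25 alone passed. At concentration 1 that block gave -2.32 for Nes, -2.45 for Olr1, -2.35 for Ptgs2 and -2.85 for Tfpi2, close to the values without it. With slide as a fixed block Tfpi2 at 1/25 was at -4.32 and did not pass (adjusted p = 0.215). No slide holds both times of a concentration, so a difference between slides stays open for all 9 genes. The same untreated arrays, with no stated time, stand for both times. Time in culture is therefore not separated from time with the drug for these genes.

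Genes lower than untreated lay mostly among the dim genes, and untreated replicate 1 is a candidate source. Without it, the median log2 change of the dimmest 10% of genes at concentration 1 for 6 h was -0.13, against -0.64 with it. An effect that grows with concentration was argued against: the 63 genes called lower at 1/5 for 24 h read 0.29 ± 0.15 higher, not lower, at concentration 1 than at 1/25. These concentrations lay on different slides at 24 h, and an effect alike at all concentrations stays open. Why that array reads dim probes higher was not tested, and a difference of that culture itself stays open.

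The many genes called for celecoxib 1/5 at 6 h may reflect the scan day. Of the called genes, 87.5% differed between the scan days in the same direction within the other groups of 6 h, against 62.5% of genes not called. Without untreated replicate 1 the called genes had a median log2 size of 1.61 against 1.79. This cannot decide whether that array alone was the source. Genes on which the untreated arrays differ have a wider spread, so they were less easily called. An effect of celecoxib at 1/5 stays open for Gldn, which passed with scan day as a block, without untreated replicate 1, and with both changes. Hs3st1 passed with the block but not without untreated replicate 1 (-2.25, adjusted p = 0.115).

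The cell cycle list was higher at 24 h than at 6 h of concentration 1 by a mean of 0.50 ± 0.10 on the log2 scale. Scan day was argued against (0.52 ± 0.09 within scan day 1). An effect that grows with concentration was argued against by -0.034 ± 0.10 between concentrations 1 and 1/25 at 24 h. These lay on different slides, so a difference between slides could hide such an effect. More fibroblasts at 24 h may contribute: the mean of their markers rose by 0.31 ± 0.12 (0.24 ± 0.13 within scan day 1). The rise over all arrays lay above a bound of 0.25, but by less than its standard error. The rule for the bound was set beforehand, and its value came from the cell cycle rise on these arrays. Of these 20 markers 10 lay above 0, 7 were saturated on at least 1 array and 3 are in another list. The 5 brightest markers saturated on no array had a median of 0.54. They were Gsn 0.08 ± 0.29, Postn -0.12 ± 0.33, Col3a1 0.56 ± 0.50, Pdpn 1.5 ± 0.30 (adjusted p = 0.0576 in limma) and Ddr2 0.54 ± 0.41. Within scan day 1 these read 0.06, -0.30, 0.08, 1.40 and 0.29. Of the 7 saturated markers, Pdgfra was at 0.13, and Mmp2 (-0.04), S100a4 (-0.08), Col1a2 (-0.06), Vim (-0.06), Col1a1 (-0.13) and Fbln2 (-0.59) read lower at 24 h. Tested between the times after seeing the data, the cell cycle list had a median of 0.54 at 1/25 (adjusted p = 9.2e-05) and of 0.28 at 1/5, where it did not pass (0.181). The means of the markers of fibroblasts, of macrophages and leukocytes and of epicardium and neural crest derived cells lay higher on all 3 arrays of 24 h than on all 3 of 6 h at each concentration, and those of smooth muscle at 1/5 and 1/25. At 1/5 the times follow the scan days exactly. Time in culture was not tested, since no untreated culture has a stated time. It stays open with the fibroblasts, other cell types, a difference between slides, and an effect of celecoxib alike at all concentrations. No slide holds both times of a concentration.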

How the results depend on the processing

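Fits with scan day as a block, within a scan day, or with quantile normalisation and scan day together were chosen after seeing the data; the other alternatives were planned. Signal over background limits the dim genes, and saturation the bright ones. For each count that moved by over 1.5 times the cause was not tested, except where fewer arrays or genes were used. Under all alternatives that gave a value and left no array out, the concentration comparison at 6 h and the difference of the concentration effects gave 0 genes in limma (1749 and 983 at an unadjusted p below 0.05).

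Normexp gave 250 genes (51 higher, 199 lower) for concentration 1 at 6 h against untreated, 3385 (1670, 1715) for 1/5 at 6 h, 234 (8, 226) for 1 at 24 h, 322 (39, 283) for 1/5 at 24 h, and, between 24 h and 6 h, 3063 (1201, 1862) at 1/5 and 1054 (469, 585) at 1/25. Quantile normalisation gave 295 (152, 143) for 1 at 6 h, 3516 (2379, 1137) for 1/5 at 6 h and 28 (12, 16) for 1 at 24 h. No filter gave 947 (311, 636) for 1/25 at 6 h, 41 (2, 39) for 1 at 24 h, 50 (10, 40) for 1/5 at 24 h, and 432 (141, 291) and 284 (124, 160) between the times at 1/5 and 1/25. The filter on all 20 arrays gave 4 (2, 2), 44 (15, 29) and 22 (6, 16) for 1, 1/5 and 1/25 at 24 h, 1 (1, 0) between concentrations at 24 h, and 2133 (1062, 1071) between the times at 1/5. The authors' table gave 9 (2, 7), 34 (13, 21) and 37 (8, 29) for 1, 1/5 and 1/25 at 24 h, and 645 (216, 429) between the times at 1/5. It also moved the share of lower genes to 43.7%, 15.4% and 20.2% for 1, 1/5 and 1/25 at 6 h. With the mean over probes no count moved by over 1.5 times.

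Slide as a random block gave 431 (86, 345), 3 (1, 2) and 15 (8, 7) for 1, 1/5 and 1/25 at 6 h, 3, 4 and 3 for the same at 24 h, and 3, 8 (2, 6) and 13 (5, 8) between the times at 1, 1/5 and 1/25. Slide as a fixed block gave 940 (142, 798) for 1 at 6 h, 2 (1, 1) for 1/5 at 6 h and 0 between the times at 1/25. It ended the call of the ATF4 list between concentrations at 24 h (0.33, adjusted p = 0.148), while the random block did not (0.28). Apart from concentration 1 against 1/25 at 24 h (0), it could not be fitted to the other comparisons. The arrays of 1 slide gave 381 (51, 330) for 1 at 6 h and no value elsewhere. The replicate block gave 44 (16, 28), 676 (478, 198) and 479 (173, 306) for 1, 1/5 and 1/25 at 6 h, and 41 (10, 31) for 1/5 at 24 h. The numbers do not pair the arrays: deviations correlated at -0.0040 on average over 57 pairs of the same number and at 0.0019 over 114 others. With only the groups compared, the counts against untreated were 0, 3511 (2184, 1327) and 0 for 1, 1/5 and 1/25 at 6 h and 0 and 0 for 1/5 and 1/25 at 24 h. Between the times they were 1 (1, 0), 8520 (4471, 4049) and 4 (0, 4). The trend over concentrations gave 0 at each time. An estimated correlation gave 0 list shifts in place of 6.

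Scan day as a block gave 2276 (495, 1781), 317 (47, 270) and 3211 (728, 2483) for 1, 1/5 and 1/25 at 6 h, 125 (24, 101), 388 (129, 259) and 237 (56, 181) for the same at 24 h, 2 (2, 0) between concentrations at 24 h, and 389 (253, 136) and 10 (5, 5) between the times at 1 and 1/5. Without untreated replicate 1 as well, it gave 38 (13, 25) for 1/5 at 6 h, 335 (63, 272) for 1/25 at 6 h, 3 (3, 0) between concentrations at 24 h, 506 (316, 190) and 9 (3, 6) between the times at 1 and 1/5, and 12 list shifts (11, 1). Within scan day 1 the counts were 1582 (233, 1349) and 2545 (674, 1871) for 1 and 1/25 at 6 h, 38 (8, 30), 226 (59, 167) and 203 (48, 155) for 1, 1/5 and 1/25 at 24 h, and 182 (131, 51) and 334 (273, 61) between the times at 1 and 1/25. There was no value for 1/5 at 6 h. Quantile normalisation with the block gave 1679 (653, 1026) and 205 (70, 135) for 1 and 1/5 at 6 h, 142 (70, 72), 657 (385, 272) and 262 (129, 133) at 24 h, and 281 (187, 94), 10 (5, 5) and 382 (267, 115) between the times.

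Leaving out each array in turn, counts ran from 5 (without untreated replicate 1) to 865 (without untreated replicate 2) for 1 at 6 h, 7 to 1527 for 1/5 at 6 h (the same arrays), 15 (without untreated replicate 1) to 4621 (without treated replicate 2) for 1/25 at 6 h, 4 to 244 for 1 at 24 h and 11 to 247 for 1/5 at 24 h (untreated replicates 1 and 2 in both), and 8 (without treated replicate 3) to 231 (without untreated replicate 2) for 1/25 at 24 h. They ran from 0 to 24 and 0 to 0 between concentrations at 6 h and 24 h, 6 to 70, 34 to 148 and 55 to 4265 between the times at 1, 1/5 and 1/25, 0 to 2 for the difference of the concentration effects, and 4 to 8 for the list shifts. An arm left with 1 array is assumed to vary like the other groups.

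Of 64 values of named genes past the threshold, 61 kept direction and threshold with normexp, 60 with quantile normalisation, 60 with the mean over probes, 52 without a filter, 52 with the authors' table, 53 with scan day as a block, 28 with the block and without untreated replicate 1, 49 with the replicate block, 25 with slide as a random block and 13 with only the groups compared. Leaving out 1 array, 174 of 339 did. Of the 6 list shifts, all 6 kept theirs with normexp, quantile normalisation, no filter and the authors' table, and 5 with scan day as a block. Direction reversed for Ptgis at concentration 1 with the authors' table (0.23 at 6 h, 0.12 at 24 h), Svs6 for 1/5 at 6 h (-0.67) and Ppp1r15a between concentrations at 24 h (-0.16) with slide as a fixed block, and Clba1 between the times at 1/5 with the scan day block (0.18, also without untreated replicate 1, and 0.01 with quantile normalisation). With the block and without untreated replicate 1, Ptgs1 (-0.10) and Ptges (0.038) reversed for 1 at 24 h. Leaving out each array in turn, Ptgs1 ran from -0.024 to 0.68 at 6 h and -0.10 to 0.60 at 24 h, Ptgis from -0.24 to 0.11 at 6 h, Ptgs2 from -1.32 to 0.16 at 24 h and Ptges from -0.66 to 0.038 at 24 h.

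The scaling moved the median log2 change of all genes. With the authors' table it was 0.25, -0.01 and 0.24 for 1, 1/5 and 1/25 at 6 h, against -0.07, -0.19 and -0.18 as planned, and 0.30, 0.29 and 0.25 at 24 h, against 0.00, -0.02 and -0.04. With quantile normalisation it was -0.07 for both 1/5 and 1/25 at 6 h.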

Other observations

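The comparisons of 24 h with 6 h at concentrations 1 and 1/25 share no array, and their genes were set side by side after seeing the data. Both take each gene's spread from the same fit, and in both some 6 h arrays but no 24 h array were scanned on day 2. The lists are therefore not independent, and the numbers for independent lists do not measure chance. Of 16 genes higher at 24 h at concentration 1 and 299 at 1/25, 12 were called at both, where independent lists would share 0.172. Of 33 and 382 lower genes, 32 were called at both (0.454 for independent lists). With scan day as a block the shared genes were 127 higher (4.40) and 59 lower (0.760). Within scan day 1 no such count is given, since 1/25 for 6 h has 1 array there.

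With and without scan day as a block, 32 genes were called in the same direction at both concentrations, 16 of them with a symbol, 5 higher and 11 lower at 24 h. Angpt1, a ligand of vascular receptors, rose by 2.01 ± 0.35 at concentration 1 and 1.99 ± 0.35 at 1/25 on the log2 scale. Nppc, a natriuretic peptide gene, was well above background on no 6 h array of either concentration and rose at least 2.25-fold and 5.12-fold. Grik2, Gjb2 and Rerg rose too, Grik2 at least 2.61-fold at concentration 1. At concentration 1 for 6 h, Angpt1 (-1.96, adjusted p = 0.0353 in limma) and Nppc (at least 3.21-fold, 0.00753) read lower than untreated. At 24 h these 2 did not pass (0.05 and -0.51), and Grik2, Gjb2 and Rerg passed at neither time. Among the lower genes, the log2 changes at concentrations 1 and 1/25 were -2.36 ± 0.41 and -2.23 ± 0.41 for Itga2, -2.33 ± 0.32 and -2.39 ± 0.32 for Nes, -1.85 ± 0.25 and -1.64 ± 0.25 for Clec14a, an endothelial surface protein, and -1.64 ± 0.31 and -1.97 ± 0.31 for Ern1, a sensor of unfolded proteins. Dlx5, Mybl1, Nap1l3, Olr1, Ptgs2, Tfpi2 and Cyp1a1 were the others. Within a concentration no slide holds arrays of both times. With slide as a random block 3 of the 32 genes passed at concentration 1, 8 at 1/25 and 3 at both, and of the 16 with a symbol none passed at concentration 1. No untreated culture has a stated time, so time in culture and time with the drug are not separated here.

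Other splits of the arrays were counted for each comparison of 3 arrays with 3, where 10 splits are too few for a share under 0.05. Between 24 h and 6 h, 1 of 10 splits gave as many genes, the real one: 49 at concentration 1 (highest other 0), 1356 at 1/5 (highest other 0) and 681 at 1/25 (highest other 2). At 1/5 the real split also parts the scan days, and the value with scan day as a block was 10. Between concentrations 1 and 1/25, where the real counts in limma were 0 (1749 genes at an unadjusted p below 0.05 at 6 h, 816 at 24 h), 10 of 10 splits gave as many at each time, as any split must when the real count is 0, so this says nothing about chance. The highest other was 9645 at 6 h and 1 at 24 h. The split with 9645 genes parts the scan days and points to that structure of the samples. No split was fitted with scan day as a block. The real comparison at 6 h gave 0 with and without it. For the difference of the concentration effects, with a real count of 0 (983 at an unadjusted p below 0.05), 100 of 100 splits gave as many, which a real count of 0 also fixes, so this test decides nothing. The highest of those was 4882, which also points to structure among the samples. That split was not fitted with the block either, and the real comparison gave 0 with and without it.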
